A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

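Gene expression was measured on 12 arrays of budding yeast RNA. Cells that carry mitochondrial DNA (ρ+) and cells that lack it (ρ0) were grown at 22 °C in complete medium with 2% glucose. Per the labels' protocols, part of each culture was harvested in glucose, and the rest was washed and shaken for 4 h in the same medium without glucose. The labels place 3 biological replicates in each of the 4 groups. Total RNA was enriched for polyadenylated RNA with oligo-dT resin, copied into double-stranded cDNA and transcribed into biotin-labelled cRNA, per the labels' protocols. The arrays were 1-colour Affymetrix yeast expression arrays.

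The deposited table holds 1 linear signal intensity per probe set and array, which the authors computed with MAS5, per the submitters' processing notes. The version and the scaling target are not given in the sources used here. The values themselves show a scaling per array: the mean signal without the lowest and highest 2% of probe sets was 99.94 on every array. The table has 9335 probe sets, of which 60 are array controls. It holds no detection calls, and the scanner files were not used here.

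Probe sets were named through the platform annotation that pairs them with genes. A single gene was listed for 6504 probe sets, several genes for 328 and none here for 2503, controls included. All 6504 gene identifiers were found in the RefSeq gene table of assembly R64, which gave current symbols for 5656 genes. No coordinates are given, since no build is stated for the array. A probe set that the array's naming marks as shared by similar transcripts stood for 260 of the genes tested, and such genes are marked as shared in the text. For a gene with several probe sets, the probe set with the highest mean signal was used.

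Signals were analysed as log2(signal + 1.498), where 1.498 is the 10th percentile of all signals. The detection level was 5.822, the 25th percentile of all signals. These percentiles were the rule set for an array without probe sets of another yeast species. As a check, 95.8% of the signals of 16 control probe sets for foreign or antisense sequences lay at or below this level, with a 95th percentile of 5.64 and a highest value of 8.79. A gene was tested if the mean of at least 1 group exceeded the detection level, which left 5361 genes. Fold changes are on the log2(signal + pseudocount) scale and understate the change of dim genes. Where a gene was at or below the detection level on all arrays of the dimmer group, its fold is given as "at least", against the detection level. No further normalization between arrays was applied.

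A means model over the 4 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, using lmFit, contrasts.fit and eBayes with an intensity trend. The fit had 8 residual degrees of freedom, and the lowest prior degrees of freedom over genes were 7.52. The 5 comparisons were glucose withdrawal in ρ+, glucose withdrawal in ρ0, ρ0 against ρ+ in glucose, ρ0 against ρ+ without glucose, and the difference of the glucose responses, ρ0 minus ρ+. P-values were two-sided and adjusted with the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Every adjusted p for a gene in the text comes from this limma fit. The labels call the replicates biological but do not say that a replicate number marks a shared culture, so the fit had no block.

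Gene lists were fixed before the data were examined, 31 in all. The 30 lists with at least 3 tested members were tested with limma's camera function at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. List members are counted as higher or lower after adjustment over all genes, and beside that after adjustment over the list alone. The named genes follow a rule fixed at the same time. It takes the 8 largest changes in each direction among called genes whose replicates did not overlap (for the difference, among called genes), the 3 members that moved most in the direction of each list past its test, 23 fixed marker genes and the genes of mitochondrial DNA. The text summarises part of them and prefers genes whose call held without any single array. Genes outside the rule stand only in the last part, which says so.

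The fit and the adjustment of p were tested on simulated signals with the real genes' means and spreads. In these, 100 genes were changed 2-fold and 100 changed 4-fold among 5361. The simulated noise was normal on the log2 scale and independent between genes and arrays. The filter and the choice of probe set were not rerun, so the false calls do not cover these steps or noise shared by genes or arrays. For glucose withdrawal in ρ+, 75% and 98% of these were recovered, with 6 false calls among 5161 unchanged genes. For ρ0 against ρ+ in glucose, 72% and 98% were recovered, with 12 false calls. For the difference of the responses, 30% and 94% were recovered, with 5 false calls. A change of 2-fold was therefore often missed in the difference.

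Alternatives set before the data were examined covered the pseudocount, a floor in its place, the filter on dim probe sets, quantile normalization, median centring, the variance model, a block for the replicate number or for the culture, fits to the 2 compared groups alone, the mean of a gene's probe sets, a 2-fold threshold, the estimated correlation and the removal of each array in turn. After the data were examined, 3 were added: removal of the 2 arrays whose hybridization controls stood apart, scaling to the polyadenylated control transcripts, and a doubled detection level. The number of arrays limits the precision of every comparison.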

Results

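Transcript levels were compared between ρ+ cells and ρ0 cells, in 2% glucose and 4 h after a shift to medium without glucose. Each of the 4 groups held 3 biological replicates on separate arrays. No group was washed and then shaken for 4 h with glucose. Loss of glucose therefore cannot be told apart from the washing or the further 4 h of shaking. Below, glucose withdrawal stands for all of these steps together. The measured value is the array signal of a probe set, the brightness left after the authors' MAS5 summary, in arbitrary units. On each array between 85.7% and 88.8% of the probe sets with a single gene exceeded the detection level, which was itself the 25th percentile of all signals. The correlation across genes between replicates of a group lay between 0.956 and 0.990. The first principal component of the 12 arrays held 40.0% of the variance and set ρ+ cells without glucose apart from the other groups, and the second held 23.2%. The median standard error of a log2 fold change was 0.21, and 0.30 for the difference of the glucose responses.

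Some measures of the arrays differed within or between groups. The bacteriophage hybridization control CreX gave a signal of 309 on the ρ0 glucose array of replicate 2 and 509 on the ρ0 array without glucose of replicate 1, against 624 to 1006 on the others. The bacterial control BioDn gave 359 and 295 on these arrays, against 460 to 668 on the others. The ratio of the 5′ to the 3′ probe set of SPT15, a sign of RNA or cDNA completeness, was 0.319 ± 0.0699 (SD, n = 3) in ρ+ in glucose and 0.188 ± 0.00577 without glucose. In ρ0 it was 0.249 ± 0.131 and 0.140 ± 0.0419. The same ratio for ACT1 differed less, at 0.70 ± 0.006 in glucose and 0.63 ± 0.033 without in ρ+, and 0.71 ± 0.10 and 0.65 ± 0.16 in ρ0. The 10 control probe sets for ribosomal RNA were higher by a mean log2 difference of 1.34 after glucose withdrawal in ρ+ (exact permutation p = 0.1, two-sided, the smallest that 20 assignments allow) and were higher by 0.84 in ρ0 (exact permutation p = 0.2). The poly-A control transcripts had a mean log2 signal of 5.27 ± 0.33 (SD, n = 3) in ρ+ in glucose and 5.14 ± 0.080 without. In ρ0 they had 5.07 ± 0.074 and 5.31 ± 0.26, and results with scaling to them carry this spread. On the authors' scale the median log2 change of all genes was −0.19 for withdrawal in ρ+, −0.11 for withdrawal in ρ0, 0.13 for ρ0 against ρ+ in glucose, 0.21 without glucose and 0.09 for the difference. Medians of gene lists in this part are given relative to these values, except where the authors' scale is named.

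The genes of mitochondrial DNA were examined first, as a check of the strain labels. OLI1, which encodes subunit 9 of the ATP synthase, gave signals of 128 ± 29.3 (SD, n = 3) in ρ+ in glucose and 128 ± 15.2 without glucose. In ρ0 they were 0.285 ± 0.131 and 0.320 ± 0.0797, below the detection level on all arrays. This is at least 21.6-fold lower in glucose (adjusted p = 1.2e-11) and at least 21.9-fold lower without (adjusted p = 1.2e-11). COX1, for cytochrome c oxidase subunit 1, measured 12.5 ± 2.01 in ρ+ without glucose and 0.689 ± 0.454 in ρ0, at least 2.12-fold lower (adjusted p = 0.000109). In glucose it measured 6.23 ± 3.57 in ρ+, above the detection level on 2 of 3 arrays, and 1.26 ± 0.499 in ρ0. Its log2 difference of −1.36 there (adjusted p = 0.0392) was no longer past the threshold without ρ+ glucose replicate 1 (adjusted p = 0.145) or 2 (0.164), ρ0 glucose replicate 1 (0.0873) or 3 (0.086), or ρ+ no glucose replicate 1 (0.0535) or 3 (0.053), nor with signals floored at the detection level (0.271), after quantile normalization or in a fit to the 2 groups alone. Of 28 probe sets for 19 mitochondrial genes, 25 were at or below the detection level on all 12 arrays, ρ+ included, in RNA selected for poly(A) tails.

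Glucose withdrawal in ρ+ cells raised gene lists for the use of other carbon sources, and the largest single changes included SPG4 and RGI2. SPG4, a gene known for its need in stationary phase, rose 55.4-fold, to 1039 ± 202 (SD, n = 3). RGI2, known for a role in respiratory growth, rose at least 56.9-fold, from below the detection level to 332 ± 26.1. The acetate and lactate permease genes ADY2 and JEN1 rose 37.4-fold and 19.5-fold, to 325 ± 57.2 and 280 ± 52.9, and the ammonium export gene ATO2 rose 19.2-fold to 416 ± 54.0. ADY2 exceeded the detection level on 2 of 3 arrays in glucose. In all, 561 genes were higher and 1193 lower of 5361 tested (270 and 274 by at least 2-fold).

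Of the 15 genes of the glyoxylate cycle, gluconeogenesis and 2-carbon use, 13 rose and none fell (13 adjusted over the list alone), with a median of 1.61 above all genes (adjusted p = 2.2e-13). ADH2, the ethanol-oxidising alcohol dehydrogenase, rose 5.04-fold to 189 ± 25.2, ICL1 for isocitrate lyase 3.27-fold to 54.8 ± 4.55, and PCK1 for phosphoenolpyruvate carboxykinase 2.80-fold to 46.9 ± 4.53. Of 12 genes of peroxisomal fatty acid oxidation, 8 rose (9 adjusted over the list alone; relative median 1.24, adjusted p = 3.6e-08). Among them, the thiolase gene POT1 rose 16.6-fold to 170 ± 10.2 and the catalase gene CTA1, above the detection level on 2 of 3 arrays in glucose, 17.3-fold to 145 ± 7.13. Of 11 glucose-repressed genes of sugar uptake and use, 10 rose (10 adjusted over the list alone; relative median 1.69, adjusted p = 7.1e-11). The hexose transporter gene HXT2 rose 6.96-fold to 1441 ± 128, and the invertase gene SUC2, on a shared probe set, 10.3-fold. Of 40 nuclear genes of the respiratory chain and ATP synthase, 20 rose (21 adjusted over the list alone; relative median 0.68, adjusted p = 1.0e-11), including INH1 for the ATPase inhibitor by 4.52-fold and QCR10 of complex III by 2.91-fold. CYC1 and COX4 of this list did not pass, with log2 values of 0.31 and 0.33 (adjusted p = 0.483 and 0.110). CIT1, from the list of retrograde targets, did not pass either (log2 0.40, adjusted p = 0.0808).

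Stress genes also rose in ρ+ cells. Of 20 general stress genes, 15 rose (17 adjusted over the list alone; relative median 1.12, adjusted p = 7.1e-11). HSP12 rose 10.7-fold to 2901 ± 464, DDR2 6.44-fold to 3150 ± 550 and HSP26 6.32-fold to 545 ± 101, while CTT1 did not pass (log2 0.67, adjusted p = 0.0678). Of 17 cytosolic chaperone genes, 9 rose and 1 fell (10 and 1 adjusted over the list alone; relative median 0.70, adjusted p = 3.3e-05). SSA4, an inducible Hsp70 gene, rose 8.33-fold to 514 ± 77.1 and HSP82, on a shared probe set, 5.30-fold to 1391 ± 83.1. Of 17 genes of oxidative stress defence, 5 rose (5 adjusted over the list alone; relative median 0.40, adjusted p = 0.00134), among them TSA2 by 3.22-fold, SOD2 by 2.08-fold and CTA1, which the peroxisomal list also holds. With an estimated correlation these 3 lists kept their call (adjusted p = 0.0308, 0.0410 and 0.0308), as did the glyoxylate, peroxisomal, sugar and respiratory lists (adjusted p = 0.00399, 0.00417, 0.0308 and 0.0410).

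Rises were seen in 4 further lists, whose calls were lost with an estimated correlation. In sulfate assimilation and methionine 4 of 14 genes rose (4 adjusted over the list alone; relative median 0.53, adjusted p = 0.00289), with MET2 up 5.15-fold and STR3 3.37-fold. In trehalose and glycogen 3 of 18 rose (3 adjusted over the list alone; 0.51, adjusted p = 0.00276), with TPS1 up 1.81-fold. In autophagy 8 of 26 rose (8 adjusted over the list alone; 0.41, adjusted p = 0.00276), with ATG8 up 3.30-fold to 655 ± 90.8 and ATG5 2.29-fold. In glycolysis and ethanol fermentation 2 of 15 rose and 0 adjusted over the list alone (0.33, adjusted p = 0.0362). This last call ended without ρ+ glucose replicate 1 (adjusted p = 0.0591), replicate 2 (0.0555) or ρ+ no glucose replicate 2 (0.127), and after quantile normalization (0.206). The adjusted p with an estimated correlation was 0.0945, 0.246, 0.0771 and 0.359 for these lists in turn.

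Lists of growth and translation genes fell in ρ+ cells, though none of these calls held with an estimated correlation. Of 80 cytosolic ribosomal protein genes 33 fell and none rose (34 adjusted over the list alone; relative median −0.11, adjusted p = 0.000888), with RPS7B 2.24-fold lower at 307 ± 19.9 and RPS28B, on a shared probe set, 3.40-fold lower. Of 91 ribosome biogenesis genes 37 fell and 1 rose (41 and 1 adjusted over the list alone; −0.30, adjusted p = 0.00134), such as UTP22 by 2.44-fold and DBP8 by 2.15-fold. Of 71 mitochondrial ribosomal protein genes 25 fell and 3 rose (25 and 3 adjusted over the list alone; −0.22, adjusted p = 0.0138), with MRPL11 2.59-fold lower. Of 15 cell cycle genes 8 fell (12 adjusted over the list alone; −0.53, adjusted p = 0.00276), among them the B-type cyclin gene CLB1 by 3.63-fold to 16.1 ± 3.43 and the polo kinase gene CDC5 by 2.20-fold. Of 24 ergosterol synthesis genes 11 fell and 1 rose (13 and 1 adjusted over the list alone; −0.26, adjusted p = 0.0437), with ERG27 1.95-fold lower. With an estimated correlation the adjusted p of these 5 lists was 0.359, 0.256, 0.437, 0.0955 and 0.367. The ergosterol call was also lost without ρ+ glucose replicate 1 (adjusted p = 0.0591) or 2 (0.0555), ρ+ no glucose replicate 2 (0.0617) or 3 (0.0642), or ρ0 glucose replicate 2 (0.0507), after median centring (0.0650) and with poly-A scaling (0.0908). The largest falls of single genes were those of the glutaredoxin gene GRX4 (5.33-fold, to 37.5 ± 3.86) and of AMN1 (4.37-fold, to 42.0 ± 3.76), which antagonises exit from mitosis.

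The split into higher and lower genes depended on the scaling of the arrays. After quantile normalization 640 genes were higher and 783 lower, after median centring 807 and 548, and with scaling to the poly-A control transcripts 443 and 309. The count of lower genes was 747 without ρ+ glucose replicate 2 and 784 without ρ+ glucose replicate 3.

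**Figure D1:**
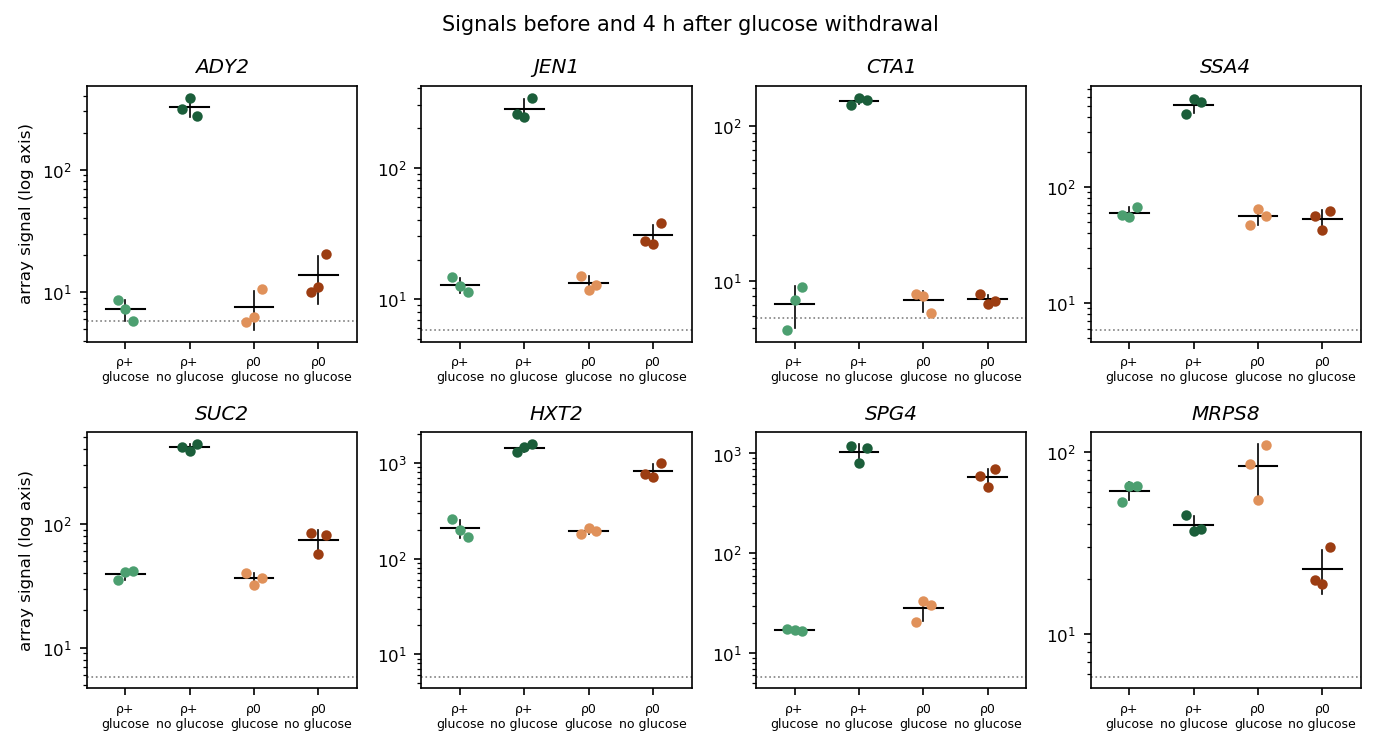
Array signals (log axis, arbitrary units) of 8 genes in the 4 groups, each point 1 array, with the mean as a horizontal line, the SD as a vertical bar (n = 3) and the detection level of 5.822 as a dotted line. ADY2, JEN1, CTA1, SSA4 and SUC2 (shared probe set) rose more in ρ+ than in ρ0, where SUC2 still rose 1.98-fold. SPG4 rose 55.4-fold in ρ+ and 19.8-fold in ρ0, HXT2 rose 6.96-fold and 4.18-fold, and MRPS8 fell 3.43-fold in ρ0.

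Glucose withdrawal in ρ0 cells raised SPG4 and sugar uptake genes and lowered genes of mitochondrial translation, but neither list call held with an estimated correlation (adjusted p = 0.173 for both). SPG4 rose 19.8-fold, from 28.1 ± 6.87 to 583 ± 119 (SD, n = 3), and RGI2 at least 6.82-fold to 40.7 ± 10.5. Of the 11 glucose-repressed sugar genes 7 rose (9 adjusted over the list alone; relative median 0.80, adjusted p = 4.1e-09). HXT2 rose 4.18-fold, and HXT6 and HXT7, on shared probe sets, 4.21-fold and 2.70-fold. Of 71 mitochondrial ribosomal protein genes 36 fell and 1 rose (52 and 1 adjusted over the list alone; relative median −0.58, adjusted p = 9.3e-13). MRPS8, MRPL49 and MRPL20 fell 3.43-fold, 3.28-fold and 3.13-fold, to 22.8 ± 6.21, 54.2 ± 10.8 and 56.0 ± 15.8.

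Other large falls in ρ0 were those of BOI1, a gene of polar growth (6.11-fold, to 7.95 ± 3.56, above the detection level on 2 of 3 arrays), the cytochrome c oxidase assembly genes PET117 (5.84-fold, to 26.5 ± 11.5) and COX10 (4.35-fold, to 11.6 ± 2.77), and the copper transporter gene CCC2 (4.72-fold, to 25.6 ± 4.39). RDN18-1, a ribosomal RNA gene on a shared probe set, was 3.87-fold higher, in RNA whose ribosomal RNA controls were higher by 0.84. In the list of cytosolic ribosomal proteins 14 of 80 genes fell (15 adjusted over the list alone; relative median −0.11, adjusted p = 0.0159). This call was lost without ρ0 no glucose replicate 1 (adjusted p = 0.0591) or 3 (0.0523), without both arrays that stood apart (0.116), after median centring (0.146) and with an estimated correlation (0.578). The list of the TCA cycle after 2-oxoglutarate passed with 2 of 7 genes higher (2 adjusted over the list alone; 0.44, adjusted p = 0.0233), but not without ρ0 glucose replicate 1 (0.0718) or ρ0 no glucose replicate 1 (0.0591), after quantile normalization (0.106) or with an estimated correlation (0.578). The Gcn4-type amino acid synthesis list passed with 1 of 32 genes higher and 1 lower and 0 adjusted over the list alone (0.26, adjusted p = 0.0159). It did not pass without ρ0 glucose replicate 3 (0.131) or ρ0 no glucose replicate 2 (0.109), after quantile normalization (0.101) or with an estimated correlation (0.578), and its median log2 value of 0.15 was −0.09 with scaling to the poly-A controls.

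Several lists that rose in ρ+ did not pass in ρ0, though the sugar list passed in both. Of 15 glyoxylate and gluconeogenesis genes 3 rose and 1 fell (4 and 2 adjusted over the list alone; relative median 0.13, adjusted p = 0.231), and of 12 peroxisomal genes 0 passed (0 adjusted over the list alone; 0.10, adjusted p = 0.461; 12 genes tested with limma). Respiratory chain genes had 2 higher and 6 lower of 40 (2 and 9 adjusted over the list alone; −0.10, adjusted p = 0.235), general stress genes 1 and 1 of 20 (0 and 0; 0.27, adjusted p = 0.231) and cytosolic chaperones 1 and 0 of 17 (1 and 0; 0.23, adjusted p = 0.231). In all, 246 genes were higher and 666 lower (63 and 201 by at least 2-fold). The counts were 86 and 331 in a fit to the 2 groups alone, 335 and 490 after quantile normalization, 444 and 382 after median centring, and 52 and 756 with scaling to the poly-A controls. Without ρ0 glucose replicate 3 they were 110 and 361, without ρ0 no glucose replicate 1 they were 128 and 384, and without ρ0 no glucose replicate 2 the higher count was 152.

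**Figure D2:**
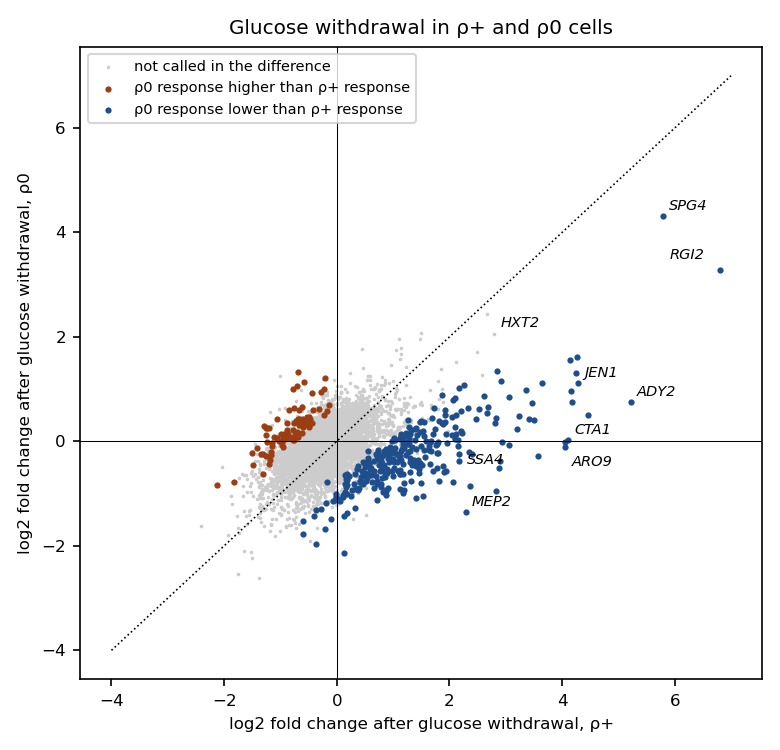
Log2 fold change of 5361 genes after glucose withdrawal in ρ0 (vertical axis) against ρ+ (horizontal axis), each point 1 gene, with the line of equal change dotted and genes called in the difference of the responses in colour. The 287 genes with a lower response in ρ0 include ADY2, CTA1, ARO9 and MEP2, and 84 genes had a higher response.

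The difference of the glucose responses tests whether ρ0 and ρ+ cells responded unlike each other. Genes of the glyoxylate cycle and peroxisomal oxidation had a lower response in ρ0, as did respiratory, stress and chaperone genes, whose list calls were lost with an estimated correlation (adjusted p = 0.0506, 0.0597 and 0.0853). In all, 287 genes had a lower and 84 a higher response. ADY2 differed by a log2 value of −4.48 ± 0.37 (SE), CTA1 by −4.09 ± 0.29, POT1 by −4.07 ± 0.34 and JEN1 by −3.17 ± 0.27. ARO9 for aromatic amino acid breakdown differed by −4.17 ± 0.27, and the ammonium permease gene MEP2 by −3.64 ± 0.26. In ρ+ in glucose ADY2 and CTA1, and in ρ0 in glucose ADY2, exceeded the detection level on 2 of 3 arrays. The adjusted p of these 6 genes lay between 4.8e-07 and 3.4e-06.

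Of 15 glyoxylate and gluconeogenesis genes 8 had a lower response (11 adjusted over the list alone; relative median −1.62, adjusted p = 1.5e-13), including ICL1 by −2.27, PCK1 by −1.89 and ADH2 by −1.70. Of 12 peroxisomal genes 7 did (7 adjusted over the list alone; −1.47, adjusted p = 2.2e-07). Both calls held with an estimated correlation (adjusted p = 0.00413 and 0.00599). Of 40 respiratory genes 15 had a lower response (25 adjusted over the list alone, with 1 higher; −0.92, adjusted p = 2.5e-14), with INH1 at −2.55, NDI1 for the internal NADH dehydrogenase at −1.89 and ATP17 at −1.80. Of 20 general stress genes 8 did (12 adjusted over the list alone; −0.96, adjusted p = 3.6e-09), with HSP12 at −2.99. Of 17 chaperone genes 4 did (4 adjusted over the list alone; −0.52, adjusted p = 0.000895), with SSA4 at −3.14 and HSP82, on a shared probe set, at −2.65. HSP12, PCK1 and MEP2 were already higher in ρ0 in glucose, which is part of their difference. HSP12 measured 1351 ± 473 there (SD, n = 3) against 268.5 ± 30.7 in ρ+, and without glucose 1824 ± 588 against 2901 ± 464. PCK1 was 2.06-fold higher in ρ0 in glucose (adjusted p = 0.0230) and MEP2 1.68-fold (adjusted p = 0.0250).

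Lower responses in ρ0 also passed for 6 lists at the preset correlation. They were sugar uptake and use (4 of 11 lower, 5 adjusted over the list alone; −0.63, adjusted p = 0.00239), sulfate assimilation and methionine (4 of 14, 5 adjusted over the list alone; −0.63, adjusted p = 0.000699), and autophagy (6 of 26, 6 adjusted over the list alone; −0.43, adjusted p = 0.00285). They also included mitochondrial ribosomal proteins (6 of 71 lower and 1 higher, 6 and 1 adjusted over the list alone; −0.37, adjusted p = 9.9e-05), trehalose and glycogen (0 of 18, 0 adjusted over the list alone; −0.38, adjusted p = 0.00844) and oxidative stress defence (2 of 17, 4 adjusted over the list alone; −0.33, adjusted p = 0.0191). Without ρ0 no glucose replicate 3 the last 2 did not pass (adjusted p = 0.0762 and 0.0697). The mitochondrial ribosomal list was already higher in ρ0 in glucose, which is part of its difference. The oxidative stress list shares CTA1 with the peroxisomal one. SUC2, on a shared probe set, differed by −2.38, HXK1 by −1.58, MET2 by −3.23 (above the detection level on 2 of 3 arrays in ρ0 without glucose) and ATG5 by −1.31. Higher responses in ρ0 passed for ribosome biogenesis (3 of 91, 3 adjusted over the list alone; 0.35, adjusted p = 1.0e-07), ergosterol synthesis (0 of 24, 5 adjusted over the list alone; 0.38, adjusted p = 0.000575), Gcn4-type amino acid synthesis (1 of 32, 1 adjusted over the list alone; 0.27, adjusted p = 0.00156) and the cell cycle (1 of 15, 1 adjusted over the list alone; 0.40, adjusted p = 0.0109). On the authors' scale the medians of these 4 lists were 0.44, 0.47, 0.36 and 0.49, and with scaling to the poly-A controls 0.09, 0.10, −0.01 and 0.15. With an estimated correlation none of these 10 lists passed, with adjusted p from 0.0853 to 0.381. Among single genes with a higher response in ρ0 were the small nucleolar RNA genes SNR74 (2.02 ± 0.30) and SNR128 (1.76 ± 0.32).

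Across genes the responses of ρ+ and ρ0 correlated with a Pearson coefficient of 0.45 (jackknife SE 0.0702) and a Spearman coefficient of 0.44, and the slope of ρ0 on ρ+ was 0.33. They share no arrays, and genes are not independent replicates. Both strains had 101 genes higher, against 25.7 expected of independent lists, and 364 lower, against 148 expected. The expected counts do not allow for the shared spread. Opposite calls were made for 32 genes, 30 of them higher in ρ+ and lower in ρ0. The count of genes with a higher response was 4 with scaling to the poly-A controls, against 352 with a lower one. The higher count was 48, 32 and 41 without ρ+ glucose replicate 1, 2 or 3, 50 without ρ+ no glucose replicate 3, 50 without ρ0 no glucose replicate 1 and 135 without ρ0 glucose replicate 2. A block for the replicate number gave 160, a block for the culture 152 and a random block for the culture 216.

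In glucose, ρ0 cells had higher levels of pleiotropic drug resistance genes than ρ+ cells, and of iron uptake genes, whose list call was lost with an estimated correlation (adjusted p = 0.156). RSB1, a gene for sphingoid base export, measured 172 ± 29.5 in ρ0 and 11.1 ± 1.28 in ρ+ (SD, n = 3), 13.7-fold higher (adjusted p = 3.3e-06). The ABC transporter gene PDR15 was 7.82-fold higher at 701 ± 309, and PDR5, another drug efflux gene, 2.63-fold higher at 1906 ± 395 against 714 ± 74.1. Of 15 genes of the drug resistance list 11 were higher (11 higher and 1 lower adjusted over the list alone; relative median 1.26, adjusted p = 8.9e-13), and the call held with an estimated correlation (adjusted p = 0.00333). PDR5 did not pass when its probe sets were averaged (adjusted p = 0.071). Of 26 genes of the iron regulon 12 were higher and 0 lower (18 and 0 adjusted over the list alone; relative median 0.50, adjusted p = 3.6e-10). The cell wall mannoprotein genes FIT2 and FIT3, linked to siderophore uptake, were 8.37-fold and 6.65-fold higher at 1406 ± 496 and 1059 ± 550, and the siderophore transporter gene ARN2 6.17-fold. FET3 did not pass (log2 0.39, adjusted p = 0.275).

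Lower in ρ0 in glucose were ZRT1, the high-affinity zinc transporter gene, at 160 ± 39.7 against 1600 ± 73.4 (10.1-fold), the hexose transporter gene HXT4 (5.21-fold), ANB1, a hypoxic form of translation factor eIF5A (5.01-fold), and the mating genes FIG1 (at least 5.34-fold) and AGA1 (3.42-fold). Of 8 retrograde targets 1 was higher (2 adjusted over the list alone), and its list did not pass (adjusted p = 0.380). CIT2 and DLD3 of that list did not pass, at log2 values of 0.10 and −0.26 (adjusted p = 0.852 and 0.548). Of 71 mitochondrial ribosomal protein genes 7 were higher (10 adjusted over the list alone; relative median 0.26, adjusted p = 2.7e-05), such as RSM28 by 1.96-fold. Of 80 cytosolic ribosomal protein genes 4 were lower (4 adjusted over the list alone; −0.36, adjusted p = 5.7e-12). In the list of general stress (Msn2/Msn4-type) 4 of 20 genes were higher (6 adjusted over the list alone; 0.12, adjusted p = 0.0227), among them HSP12 4.84-fold at 1351 ± 473 and DDR2 2.51-fold. That call was lost without ρ+ glucose replicate 2 (adjusted p = 0.0638), ρ0 glucose replicate 2 (0.131) or 3 (0.0509), and without both arrays that stood apart (0.154). With an estimated correlation the adjusted p of these 3 lists was 0.435, 0.196 and 0.435.

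Lower medians relative to all genes in glucose passed for 4 more lists, none of them with an estimated correlation. They were glucose-repressed sugar uptake and use (3 of 11 lower, 3 adjusted over the list alone; −0.21, adjusted p = 0.0227; 0.435 with an estimated correlation), sulfate assimilation and methionine (1 of 14, 1 adjusted over the list alone; −0.28, adjusted p = 0.0193; 0.305), ergosterol synthesis (1 of 24 higher, 1 adjusted over the list alone; −0.21, adjusted p = 0.0432; 0.435) and vacuolar H+-ATPase (0 of 14, 0 adjusted over the list alone; −0.19, adjusted p = 0.0452; 0.435). Their medians on the authors' scale, −0.08, −0.14, −0.07 and −0.06, were 0.12, 0.05, 0.13 and 0.14 with scaling to the poly-A controls. Without ρ+ glucose replicate 1 none of the 4 passed (adjusted p = 0.0999, 0.0652, 0.0652 and 0.0999). Without ρ+ glucose replicate 2 the ergosterol and vacuolar calls were lost (0.0779 and 0.0790). Without ρ0 glucose replicate 1 or 3 the sugar (0.0622 and 0.144), ergosterol (0.0908 and 0.261) and vacuolar (0.0649 and 0.270) calls were lost. Quantile normalization also ended these 3 calls (0.0526, 0.252 and 0.404), and poly-A scaling the ergosterol and vacuolar calls (0.0977 and 0.107). In all, 268 genes were higher and 78 lower in ρ0 in glucose (80 and 31 by at least 2-fold). The counts were 136 and 105 after quantile normalization, 118 and 160 after median centring, and 312 and 22 with scaling to the poly-A controls. They were 138 and 30, 116 and 27, and 122 and 34 without ρ+ glucose replicate 1, 2 or 3, and 149 and 48 without ρ0 glucose replicate 1.

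**Figure D3:**
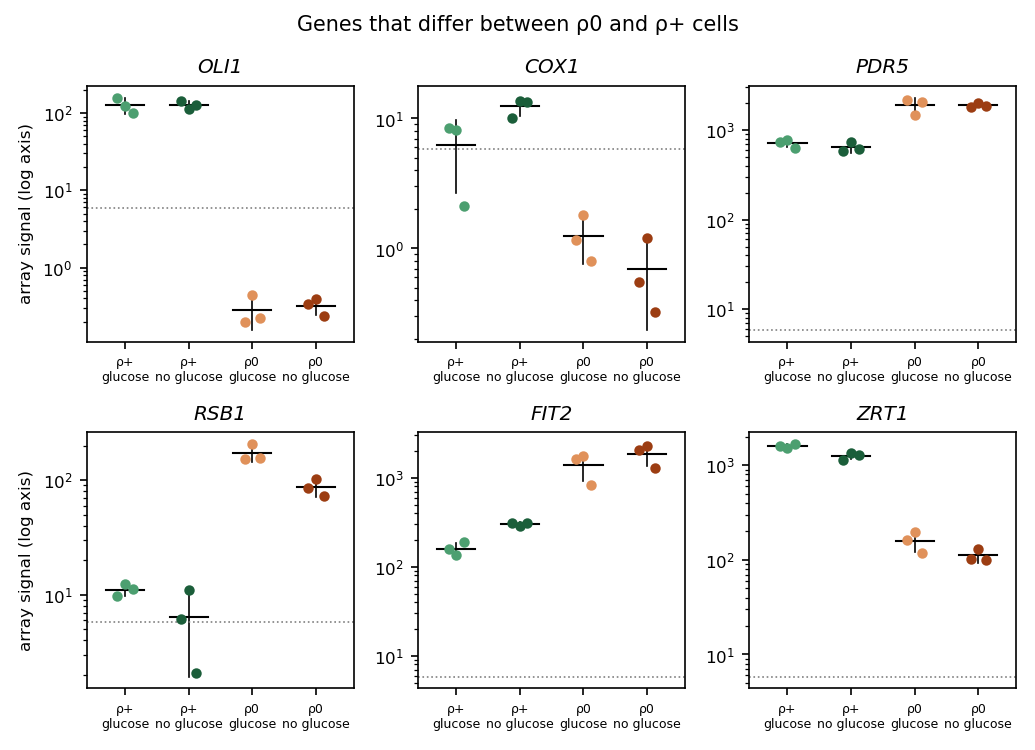
Array signals (log axis, arbitrary units) of 6 genes in the 4 groups, each point 1 array, with the mean as a horizontal line, the SD as a vertical bar (n = 3) and the detection level of 5.822 as a dotted line. OLI1 and COX1 of mitochondrial DNA and ZRT1 were lower in ρ0, while PDR5, RSB1 and FIT2 were higher in both media.

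Without glucose, ρ0 cells had lower levels than ρ+ cells of glyoxylate, peroxisomal, respiratory, sulfate and oxidative stress genes, and higher levels of drug resistance genes. Sugar, general stress and chaperone genes were also lower, but these list calls were lost with an estimated correlation (adjusted p = 0.0590, 0.104 and 0.0930). ADY2 was 21.9-fold lower at 13.9 ± 5.86 against 325 ± 57.2 (SD, n = 3), CTA1 16.1-fold and JEN1 8.77-fold lower, with adjusted p between 5.6e-09 and 2.4e-08. Of 15 glyoxylate and gluconeogenesis genes 12 were lower (12 adjusted over the list alone; relative median −1.46, adjusted p = 2.9e-13), and of 12 peroxisomal genes 8 were lower (8 lower and 1 higher adjusted over the list alone; −1.22, adjusted p = 2.7e-07). Of 40 respiratory genes 23 were lower and 2 higher (26 and 2 adjusted over the list alone; −0.96, adjusted p = 2.5e-16), with INH1 7.36-fold lower, ATP17 4.64-fold lower and COX4 2.19-fold lower. Of 14 sulfate and methionine genes 7 were lower (8 adjusted over the list alone; −1.01, adjusted p = 2.7e-07), with MET2 11.2-fold lower (above the detection level on 2 of 3 arrays in ρ0) and STR3 3.43-fold lower. Of 17 oxidative stress genes 5 were lower and 1 higher (5 and 3 adjusted over the list alone; −0.60, adjusted p = 0.00116). These 5 calls held with an estimated correlation (adjusted p = 0.00446, 0.00642, 0.0211, 0.0149 and 0.0263). The peroxisomal and oxidative stress lists share CTA1, so their calls are not independent.

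Of 15 drug resistance genes 12 were higher (12 adjusted over the list alone; relative median 1.35, adjusted p = 5.0e-08; 0.00651 with an estimated correlation). RSB1 was 12.5-fold higher at 86.6 ± 14.7 against 6.40 ± 4.47, the latter above the detection level on 2 of 3 arrays, PDR15 was 6.36-fold higher, and PDR3, a regulator of the list, 4.04-fold higher at 134 ± 13.4. Of 26 iron regulon genes 18 were higher and 2 lower (19 and 2 adjusted over the list alone; 0.59, adjusted p = 8.3e-05; 0.155 with an estimated correlation), with ARN2, FIT3 and FIT2 9.17-fold, 6.16-fold and 5.96-fold higher. Between the media, 135 genes were higher in ρ0 in both, against 55.1 expected of independent lists, and 34 lower in both, against 7.33 expected. Opposite calls were made for 24 genes. The strain differences in the 2 media share no arrays and correlated across genes with a Pearson coefficient of 0.34 and a Spearman coefficient of 0.30. Their calls share the spread per gene, for which the expected counts do not allow.

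Of 11 glucose-repressed sugar genes 8 were lower without glucose (8 adjusted over the list alone; −1.09, adjusted p = 1.9e-07), with SUC2, on a shared probe set, 5.61-fold lower. Of 20 general stress genes 8 were lower and 2 higher (9 and 2 adjusted over the list alone; −0.73, adjusted p = 1.2e-05), with HSP26 4.76-fold lower and HSP42 4.16-fold lower. Of 17 chaperone genes 6 were lower and 1 higher (6 and 1 adjusted over the list alone; −0.43, adjusted p = 0.000724), with SSA4 9.40-fold lower. Of 91 ribosome biogenesis genes 39 were higher and none lower (49 adjusted over the list alone; 0.32, adjusted p = 2.4e-06), with RRP9 2.31-fold and DBP10 2.21-fold higher. Of 15 cell cycle genes 8 were higher (9 adjusted over the list alone; 0.52, adjusted p = 0.00511), such as CDC20 by 2.08-fold, and of 32 amino acid synthesis genes 14 were higher (15 adjusted over the list alone; 0.25, adjusted p = 0.00154), such as SER3 by 2.23-fold. The last 3 calls were also lost with an estimated correlation (adjusted p = 0.105, 0.117 and 0.395). So were those of the cytosolic ribosomal proteins (5 of 80 lower, 0 adjusted over the list alone; −0.32, adjusted p = 0.00131; 0.393 with an estimated correlation), which also did not pass after quantile normalization (0.139), of ergosterol synthesis (8 of 24 higher, 9 adjusted over the list alone; 0.21, adjusted p = 0.0445; 0.393) and of autophagy (6 of 26 lower and 2 higher, 6 and 2 adjusted over the list alone; −0.24, adjusted p = 0.0231; 0.141). The autophagy call ended without ρ+ no glucose replicate 2 (0.0762), with a filter on the mean of all arrays (0.110) and with a doubled detection level (0.0554). The ergosterol call ended without ρ+ no glucose replicate 2 (0.0762) or 3 (0.0680) and without ρ0 no glucose replicate 1 (0.0539) or 2 (0.142). It also ended without both arrays that stood apart (0.0562), with the filter on the mean (0.0527), the doubled detection level (0.0554), median centring (0.0872) and poly-A scaling (0.129).

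In all, 1102 genes were higher and 504 lower in ρ0 without glucose (237 and 234 by at least 2-fold). The counts were 601 and 574 after quantile normalization, 442 and 740 after median centring, and 222 and 397 with scaling to the poly-A controls. Without ρ0 no glucose replicate 1 the higher count was 701.

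**Figure D4:**
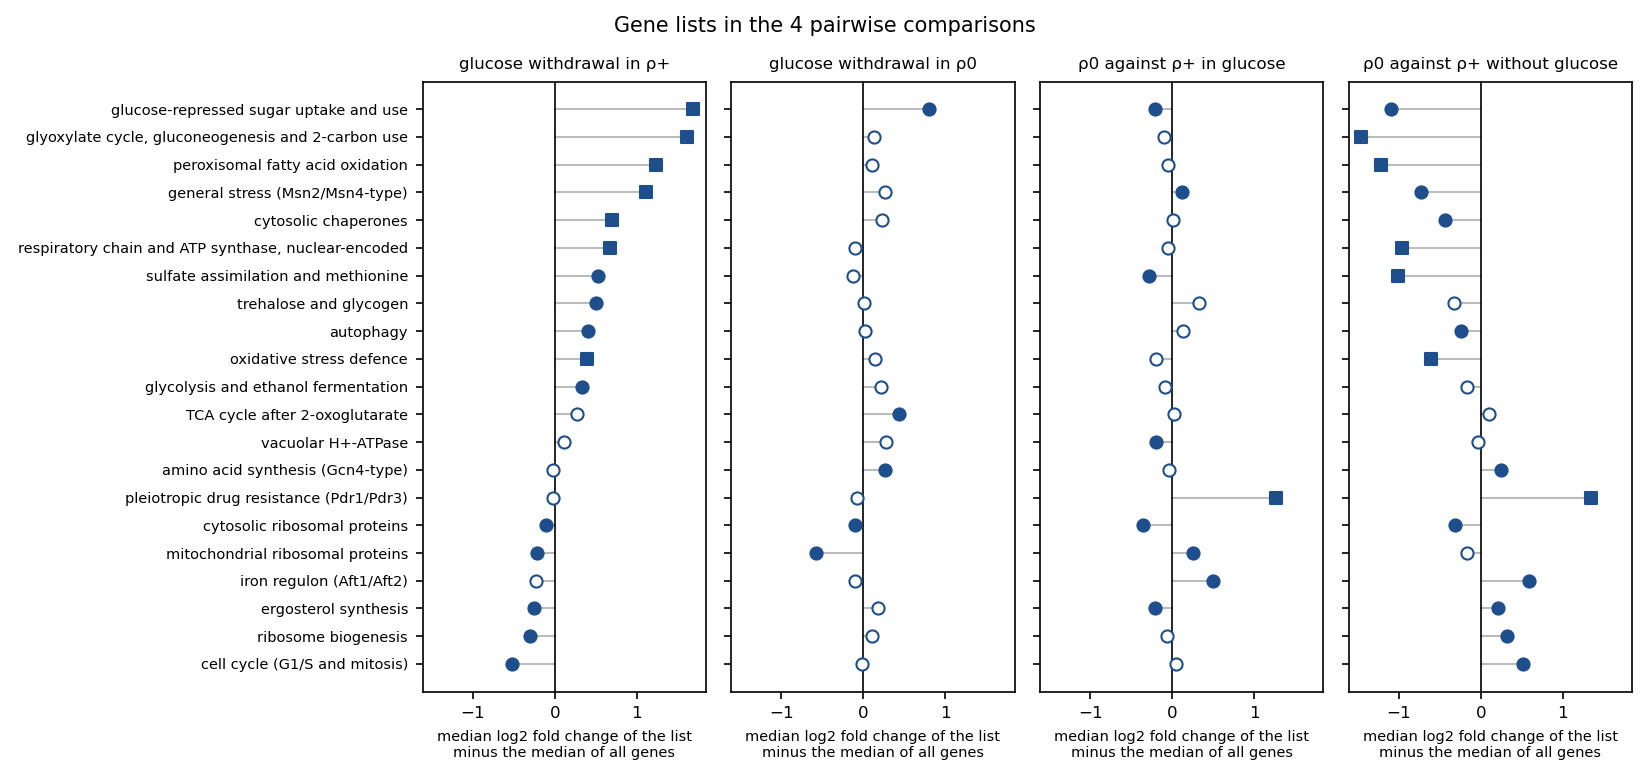
Median log2 fold change of each gene list minus the median of all genes (horizontal axis) in the 4 pairwise comparisons. Filled symbols passed the test at the preset correlation, squares also with an estimated correlation, and open circles neither. The respiratory list passed both tests at 0.68 for withdrawal in ρ+ and neither at −0.10 for withdrawal in ρ0.

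Some lists did not pass in any of the 5 comparisons. Their lowest adjusted p was 0.148 for the 8 retrograde targets (1 gene higher in ρ0 after withdrawal, 0 adjusted over the list alone; without glucose 3 were higher in ρ0 than in ρ+, 3 adjusted over the list alone), 0.195 for 31 mitochondrial import genes (2 lower in the difference, 2 adjusted over the list alone), 0.138 for 14 genes induced by hypoxia or heme depletion (4 lower and 1 higher in ρ0 without glucose, 4 and 2 adjusted over the list alone) and 0.0544 for 10 phosphate starvation genes (3 higher in ρ+ after withdrawal, 3 adjusted over the list alone). It was 0.271 for 34 proteasome genes and 0.217 for 4 histone genes. Among lists that serve as cell type or strain markers, it was 0.298 for 12 mating type genes, 0.577 for 7 meiosis genes and 0.541 for 6 auxotrophic marker genes. The list of mitochondrial DNA had 2 tested genes and no list test. For every list past its test, the median relative to all genes had the sign of the test.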

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

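List medians in this part are on the authors' scale, not relative to all genes. Both tests of an evenly compressed response were chosen after the results had been seen, and removal of the 2 arrays and scaling to the poly-A controls were added after the arrays had been examined.

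The rise of glyoxylate and gluconeogenesis genes after glucose withdrawal was smaller in ρ0, with a median difference of −1.53. It was −1.63 without the 2 arrays whose hybridization controls stood apart, and −1.55 where it came nearest 0 over 3 scalings, so neither accounts for it. A response compressed alike for every gene was tested first by the count of larger responses of the same sign in ρ0, and the 14 genes found (all lower) among 371 called stayed within the 18.6 that the false discovery rate allows, so this test did not exclude it. A second test was added once that outcome was known, with the sugar list picked after the shares kept by 9 lists had been seen. In it ρ0 kept 61.7% ± 15.2 (jackknife SE) of the ρ+ response in the sugar list and 6.12% ± 4.03 in the glyoxylate list. These shares lay 55.6 ± 16.1 points apart. Members of the sugar list differed. HXT7 changed by log2 1.24 in ρ+ and 1.43 in ρ0, and SUC2 by 3.36 and 0.98, both on shared probe sets. HXT6 and HXT7 started 2.73-fold and 2.11-fold lower in ρ0 in glucose. The 32 genes called in opposite directions cannot decide the question, since false calls in ρ0 could give such pairs. Their number was not set against the false calls allowed among the 912 genes called in ρ0. Of the other lists, the mitochondrial ribosomal proteins kept 188% ± 50.1 and the cytosolic ones 67.5% ± 24.0. The respiratory list kept −32.5% ± 18.4, which lies within 2 SE of 0. Shares near the glyoxylate one were kept by peroxisomal (0.292% ± 3.77), general stress (6.03% ± 14.2), chaperone (5.18% ± 15.0) and ribosome biogenesis genes (−5.47% ± 27.3). The list test of the difference gave the mitochondrial ribosomal proteins an adjusted p of 9.9e-05, and 0.239 with an estimated correlation. This list was already higher in ρ0 in glucose, by a median of 0.39. Set against the glyoxylate share, those of the sugar list and the mitochondrial ribosomal proteins argue against an even compression, for these lists alone. Both were singled out after all 9 shares had been seen. The first test cannot decide the question, since a low count of larger responses does not show that every gene kept an equal share.

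Drug resistance genes were higher in ρ0 in glucose, with a list median of 1.40. It was 1.29 without the 2 arrays and 1.23 where it came nearest 0 over the scalings, under median centring. Neither explanation accounts for the result, and a difference between the strains other than mitochondrial DNA was not tested.

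Iron regulon genes were higher in ρ0 in glucose, with a list median of 0.63. It was 0.74 without the 2 arrays and 0.46 under median centring. The call was lost with an estimated correlation (adjusted p = 0.156), so the list could owe its call to genes that vary together.

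The responses differed in 84 genes higher and 287 lower in ρ0, but in 4 and 352 with scaling to the poly-A controls, and the higher count was 32 without ρ+ glucose replicate 2 and 216 with a random block for the culture. Of the lists named next, all but peroxisomal oxidation lost their call with an estimated correlation. The list medians were −0.83 for the respiratory chain, −1.38 for peroxisomal oxidation, −0.54 for sugar use, −0.29 for trehalose and glycogen, −0.87 for general stress, −0.43 for chaperones, −0.24 for oxidative stress, −0.28 for mitochondrial ribosomes, −0.54 for sulfate and −0.34 for autophagy. They were 0.44 for ribosome biogenesis, 0.47 for ergosterol, 0.36 for amino acid synthesis and 0.49 for the cell cycle. With scaling to the poly-A controls these 4 were 0.09, 0.10, −0.01 and 0.15.

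Control probe sets for ribosomal RNA were higher by 1.34 after withdrawal in ρ+ (exact permutation p = 0.1), and their cause was not tested. Of 1526 probe sets without a single named gene, 155 were called in that comparison, 109 higher and 46 lower, and they were not examined further.

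Regrouping the arrays gave 10 splits per comparison, and the real split was the only 1 of 10 to reach its count in each of the 5 comparisons, but 10 splits are too few for a share under 0.05. The real count and the highest other count were 1754 and 0 for withdrawal in ρ+, 912 and 176 for withdrawal in ρ0, 346 and 0 for the strains in glucose, 1606 and 0 without glucose, and 371 and 0 for the difference. Every other split mixed arrays of the real groups, so real differences widened the spread per gene. Low counts were therefore likely beforehand and say little about chance.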

How the results depend on the processing

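Scaling to the poly-A controls, removal of the 2 arrays that stood apart and a doubled detection level were chosen after results had been seen. Of 9183 alternative values for the named genes, called or not, 281 lost a call and 64 gained one. Of 4110 for lists, called or not, 57 lost a call and 37 gained one, not counting the estimated correlation, which ended most list calls. No called test reversed direction, though some list medians changed sign with the scaling. The cause was not tested for any changed result.

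Scaling, removal of single arrays, the fit to 2 groups and the 2-fold threshold each moved some counts. Quantile normalization gave 783 lower genes for withdrawal in ρ+, 136 higher in ρ0 in glucose and 601 higher in ρ0 without glucose. Median centring gave 548 lower for ρ+ withdrawal, 444 higher and 382 lower for ρ0 withdrawal, 118 higher and 160 lower in glucose, and 442 higher without glucose. Poly-A scaling gave 309 lower for ρ+ withdrawal, 52 higher for ρ0 withdrawal, 22 lower in glucose, 222 higher without glucose and 4 higher in the difference. A fit to the 2 groups alone gave 86 higher and 331 lower for ρ0 withdrawal.

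A 2-fold threshold left 544, 264, 111 and 471 genes in the 4 pairwise comparisons. With an estimated correlation 7, 0, 1, 6 and 2 lists passed in the 5 comparisons.

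Leaving out each array in turn gave ranges of 407 to 633 higher and 747 to 1355 lower genes for ρ+ withdrawal, 110 to 356 and 361 to 769 for ρ0 withdrawal, 116 to 284 and 27 to 84 in glucose, 701 to 1265 and 391 to 567 without glucose, and 32 to 135 and 198 to 328 for the difference. The correlation of the responses ranged from 0.41 to 0.48.

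The labels do not say that a replicate number marks a shared culture, and the values did not establish it: only 2 of 6 same-strain arrays correlated best with the array of their own number in the other medium (0.52 for ρ0 replicate 3), and the consensus correlation within a culture was 0.19. A block for the number gave 160 higher genes in the difference, a block for the culture 152 and a random block for the culture 216. For ρ0 withdrawal the counts were 348 and 832, 367 and 851, and 356 and 899. List tests were not run with the random block.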

Other observations

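The genes in this part were chosen after their values had been seen, so their p-values are descriptive. Of 7 nitrogen use genes examined, only MEP2 was called in opposite directions in the strains. MEP2, for the high-affinity ammonium permease, rose 4.88-fold after glucose withdrawal in ρ+ (39.3 ± 3.85 to 198 ± 13.6, SD, n = 3, adjusted p = 3.3e-07) and fell 2.55-fold in ρ0 (67.7 ± 12.4 to 25.6 ± 4.57, adjusted p = 0.000279). GAP1, for the general amino acid permease, rose 3.38-fold in ρ+ and did not pass in ρ0 (log2 −0.08, adjusted p = 0.844). DAL5, for an allantoate permease, rose 2.02-fold in ρ+ to 50.2 ± 8.26 and did not pass in ρ0 (log2 −0.40, adjusted p = 0.201). The aromatic aminotransferase gene ARO9 reached 141 ± 5.85 in ρ+ and 10.9 ± 1.26 in ρ0 without glucose, and the decarboxylase gene ARO10 reached 25.8 ± 2.18 in ρ+ but stayed below the detection level in ρ0. MEP3 fell in both strains, 2.44-fold and 3.06-fold, and MEP1 passed in neither.

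Of 5 zinc genes examined, only ZRT1 passed as lower in ρ0 in both media, though all 5 had negative log2 values in both. Without glucose ZRT1 was 11.3-fold lower, at 111 ± 17.9 against 1263 ± 104 (adjusted p = 6.8e-09). ZRT2, for the low-affinity transporter, was 2.29-fold lower in glucose (adjusted p = 0.00140) and did not pass without glucose (log2 −0.21, adjusted p = 0.402). ZRT3, ZRC1 and the regulator gene ZAP1 did not pass between the strains.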
